A study of Mus musculus with 38 samples.

How the data were processed

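Spleen RNA of 38 BXD strains was measured on 38 single-colour Illumina Mouse-6 v1.1 arrays, 1 array per strain, each hybridised with RNA pooled equally over 2 mice of one sex aged 8 to 12 weeks, per the labels. The labels give 35 arrays as male and 3 as female. Spleens were kept in a stabilising reagent before total RNA was extracted, per the labels' protocols. Immunophenotypes by flow cytometry were used for the 34 strains that have both an array and a phenotype entry. Per the series text, mice of both sexes were phenotyped, 4 per sex and strain on average. The tissue and gates of the flow cytometry, and whether mice of the array pools were among those phenotyped, were not given in the sources used here.

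The table deposited by the authors holds bead-averaged probe intensity values that were not normalized between arrays, with a detection p-value per probe and array, per the file headers. The scanner software and the rule behind the detection p-values were not given in the sources used here. The authors also deposited a table of processed values on a log2-like scale, for which lumi is named in the submitters' processing notes without a version. Its column medians ran from 7.83 to 7.86, and its values at the low end were compressed, so its transformation stayed unknown; it was neither centred nor expressed as a ratio. Each of the 38 arrays correlated best with its own column of that table. The phenotype table deposited by the authors gives CD3+, CD79+ and CD8+ cells as percent of lymphocytes, averaged per strain. The CD4+ column of that deposited table is also a percent per the labels, but the entry of BXD33 lies above 100 and was not used. Per the labels, the traits LN T:B, LN CD4:CD8 and LN MHC Med are natural log values. They are of the ratio of T to B cells, of the ratio of CD4+ to CD8+ cells and of the median level of MHC class II on B cells. The number of mice behind each strain's trait value is not in the deposited table, so no error could be attached to a trait.

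Intensities were background-corrected and quantile-normalized on the log2 scale with neqc of limma 3.58.1 (offset 16) in R 4.3.3, with the detection p-values standing in for negative controls; tables were read with data.table (version 1.17.8). Of 34492 probes, 16507 with a detection p-value under 0.01 on at least 3 arrays were kept. GEO's platform annotation gave 1 gene symbol for 20256 probes, several for 9 and none for 14227. Of the probes kept, 11442 had 1 symbol, for 10400 genes, and 5059 had none and are unnamed here. Entrez identifiers of 20213 of the probes with 1 symbol were found in a gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names, chromosomes and neighbouring genes. Each array had 12213 to 14162 probes detected (median 13217.5), and 9320 probes were detected on every array. Median intensity ran from 85.0 to 121.6 against 67.9 to 96.9 for undetected probes of the same arrays. The number of arrays limits the precision of every value, and because each strain has 1 pool, p-values measure the spread between strains, which holds technical error too.

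The detection p-values as deposited are not a function of intensity for some probes. Of 231278 values above an intensity of 500, 18836 had a detection p-value of 0.01 or more, in 1144 probes, and 156 probes above that intensity on every array were not kept while 3884 were. The background that neqc estimated from them had a mean of 134 to 207 and an SD of 236 to 582 across arrays. Values near background were therefore compressed, and slopes of dim probes are smaller than with a narrower background. An alternative chosen after seeing the data replaced each detection p-value by a running median over 201 probes ordered by intensity. Its background had a mean of 68.4 to 97.6 and an SD of 9.90 to 14.6, and it kept 17584 probes, 16324 of them also kept as designed. Slopes under that alternative are given beside each value that it moved by more than 1.5 times.

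The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be added later. For each trait, log2 intensity was fitted on the trait, scaled to its SD, with lmFit and eBayes of limma over the 34 strains, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. A slope is therefore a log2 difference per 1 SD of the trait, and its error is a standard error. With the probe of highest mean per gene, 26 gene lists were tested with camera of limma at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. The lists covered T cells, B cells, CD4 T cells, CD8 T cells, MHC class II and class I presentation, interferon response, NK and cytotoxic cells, macrophages, neutrophils, dendritic cells, erythroid cells, megakaryocytes and platelets, cell cycle, plasma cells, germinal centre, marginal zone B cells, stroma and capsule, pancreas, adipose tissue, ribosomal proteins, oxidative phosphorylation, immediate early genes, heat shock, glucocorticoid response and the circadian clock. A list of Y-linked genes and Xist served to check the sex labels and was not tested. Arrays labelled female were compared with those labelled male with limma over all 38 arrays.

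Pairs of traits were compared with Pearson's r and Spearman's rho and two-sided permutation tests of 100000 resamples, adjusted over the 3 pairs. Coexpression of each list was measured as the mean pairwise r over 38 arrays and set against 10000 random lists of the same size matched on mean expression, one-sided. The 3000 probes of largest SD were clustered by average linkage on 1 minus r, and groups formed at a height of 0.5 with at least 20 probes were taken as modules. The first principal component of each module was set against each trait with permutation tests, adjusted over 60 pairs. The 100 genes of smallest p per trait were tested for each chromosome with one-sided Fisher's exact tests against the 10385 genes kept with a chromosome. Added after seeing the data were relations within the levels of H2 genes, 27 relations with the pancreas score and 20 with the erythroid score, where the 2 arrays left out are those farthest from the score's median. List members within modules were tested, as an addition, with one-sided Fisher's exact tests against the 2062 named genes clustered. Named genes per trait are the 12 of smallest p per direction past the threshold, or the 10 of smallest p where fewer than 10 probes passed. To these come 14 lymphocyte and MHC genes in every trait, and up to 4 members of each list past its test. Further named genes are the 10 of smallest p for labelled sex with the Y-linked list, up to 6 genes per module and per over-represented chromosome, the 20 of largest SD and up to 4 members of each coexpressed list. Genes named for a trait outside the lists are each given by their probe of smallest p. Of these, the ones that describe a result are printed. Among the 14, Cd8a was not on the probe table, and the 1 Cd4 probe was detected on 0 arrays with the deposited detection p-values and was not kept.

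Alternatives were the authors' processed table, no background correction, all probes and probes detected on every array. Others were labelled sex or the first principal component as a covariate, arrays labelled male only, fits without the 2 strains farthest from the trait's median, normal scores, the cell percentages in place of the ratios, other tree heights and numbers of probes, Spearman's rho and each array labelled female left out in turn. Added after seeing the data were the smoothed detection p-values, the pancreas or erythroid list score as a covariate, the other trait as a covariate, the 15 strains with a mean pancreas list value under 9, and the authors' table without BXD12. Slide as a block was not run, since no slide is given in the file headers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

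The fits of traits and labelled sex, the list tests, coexpression, modules, module and trait pairs and chromosomes were tested on simulated data. These stood for normalized and filtered values and were drawn independently for each probe with the mean and SD of the real one. Correlation between genes of the same kind as in the arrays was therefore not part of the test. Background correction, the detection filter, the correlations between traits and the relations added later were not simulated. Of probes planted at a slope of 1 of their own SD per trait SD, limma called 93% for LN T:B, 97% for LN CD4:CD8 and 92% for LN MHC Med. At 0.5 SD it called 8%, 22% and 17%. Among the unchanged of 16507 probes it made 5, 3 and 6 calls. Both lists of each trait planted at 0.5 SD were called by camera and by fry, and camera called 1, 0 and 1 other lists. For 3 arrays against 35, 31% of probes planted at 2 SD and 99% of those at 4 SD were called, with 9 other calls. The coexpressed list, the 4 modules and the chromosome that had been planted were each recovered, with 0 other lists called. For module and trait pairs the planted pair was called, with 3 other pairs, 2 of them in modules with nothing planted; over 100 sets of 20 random components, 6 sets gave any call.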

Results

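Spleen gene expression was measured in 38 BXD strains, recombinant inbred mouse lines that each carry a fixed mosaic of the C57BL/6 and DBA/2 genomes. Strains therefore differ in the parental allele they hold at each locus. Each strain was represented by 1 array of pooled RNA from 2 mice, and the strain was the replicate throughout. The arrays were labelled male for 35 strains and female for BXD18, BXD38 and BXD96. For 34 strains flow cytometry gave 3 traits. LN T:B is the natural log of the ratio of CD3+ T cells to CD79+ B cells, and LN CD4:CD8 that of CD4+ to CD8+ cells. LN MHC Med is the natural log of the median MHC class II level on B cells. BXD70, BXD75, BXD83 and BXD87 had an array and no phenotype used here. The arrays had 12213 to 14162 probes detected each, and 16507 probes, for 10400 named genes and for sequences without a name here, were analysed.

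Among the most variable named genes across the 38 arrays was H2-Ea, which encodes the alpha chain of the MHC class II E molecule. Its SD was 3.94, and its log2 intensity ran from 7.74 to 15.94. Most of the 20 most variable genes were instead genes of pancreatic secretory cells. The elastase gene Cela2a had an SD of 3.57 (range 7.75 to 15.94), the chymotrypsinogen gene Ctrb1 of 3.57, the carboxypeptidase gene Cpa1 of 3.42 and the zymogen granule gene Zg16 of 3.32. The order of these SDs is not read, as H2-Ea and the enzyme genes ran from background to the top of the scale. In all, 13 of the 20 belonged to the pancreas list. Of the other 7, the trypsinogen gene Prss1, the amylase gene Amy2a5, Rnase1, Tff2 and Dmbt1 followed that list's score over the 38 arrays. Their r lay between 0.859 (Amy2a5; rho 0.916; r without the 2 farthest arrays 0.861) and 0.996 (Prss1; rho 0.977; r without the 2 farthest arrays 0.997). Each permutation p was 1.0e-05, the smallest these permutations can give (adjusted over 27 relations with the score 3.9e-05). H2-Ea (r = 0.25, permutation p = 0.127; rho 0.0364, permutation p = 0.827) and Fcer1g (r = -0.196, permutation p = 0.235; rho -0.162, permutation p = 0.332) did not follow it. Without the same 2 arrays their r was 0.298 and -0.192.

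The mean of the 16 measured pancreas list genes ran from 7.80 in BXD48 to 15.06 in BXD28. It was under 9 on 18 arrays and at least 9 on 20. Values of these markers of another organ are given beside the gene groups with which they moved.

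**Figure D1:**
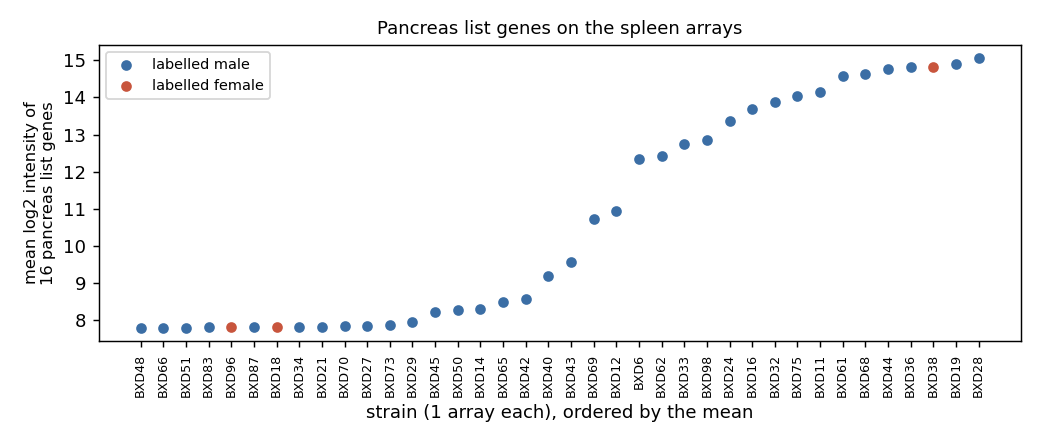
Mean log2 intensity of the 16 measured pancreas list genes on each of the 38 arrays, 1 point per strain, ordered by that mean. The values run from 7.80 in BXD48 to 15.06 in BXD28, with 18 arrays under 9.

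Across the 34 strains LN T:B averaged -0.635 (SD 0.543), from -2.11 in BXD98 to 0.442 in BXD6, so that B cells outnumbered T cells in the average strain. LN CD4:CD8 averaged 0.48 (SD 0.293), from -0.007 in BXD98 to 1.15 in BXD44. LN MHC Med averaged 3.65 (SD 0.294), from 3.02 in BXD65 to 4.15 in BXD24.

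Strains with a higher ratio of T to B cells had more MHC class II per B cell. Over the 34 strains r between LN T:B and LN MHC Med was 0.598 (95% interval 0.325 to 0.779, permutation p = 0.00023, adjusted over the 3 pairs of traits 0.00069). Spearman's rho was 0.643 (permutation p = 9.0e-05, adjusted 0.00027). Without BXD98 and BXD14, the strains farthest from the median LN T:B, r was 0.632, and over the 31 strains with an array labelled male it was 0.57. The ratio of CD4+ to CD8+ cells showed no relation to either of the other traits that passed its test. Its r with LN T:B was -0.0005 (95% interval -0.339 to 0.338, permutation p = 0.998, adjusted 0.998), and rho was -0.039 (permutation p = 0.824). Without BXD98 and BXD14 that r was -0.0844. Its r with LN MHC Med was -0.12 (95% interval -0.44 to 0.227, permutation p = 0.498, adjusted 0.747), and rho was -0.133 (permutation p = 0.451). Without BXD44 and BXD43 that r was -0.0762.

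**Figure D2:**
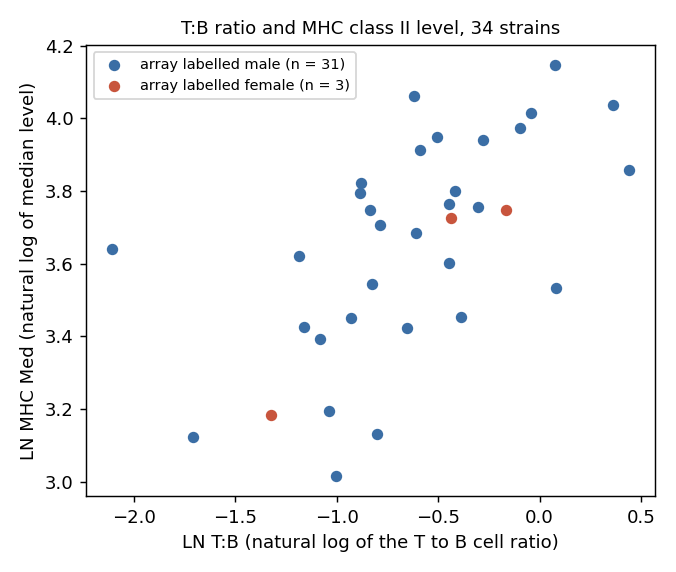
LN T:B against LN MHC Med (both natural log values) for 34 strains, 1 point per strain, coloured by the labelled sex of the strain's array. Points rise from left to right, with r = 0.598.

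The series sets spleen expression against these traits, and the first comparison asked which transcripts track the level of MHC class II on B cells. H2-Ea was higher in strains with more MHC class II per B cell. Its slope was 2.85 ± 0.47 (log2 per SD of LN MHC Med, SE, n = 34; limma adjusted p = 0.0041). As H2-Ea lay at background or at the top of the scale on most arrays, the size of this slope depends on those limits and on where background is set. With smoothed detection p-values it was 3.65 (adjusted p = 0.0022). Probes of several other genes of antigen presentation gave lower signal in those strains. Strain variants under these probes could not be told apart from lower expression, here and in the gene lists and traits below. H2-Ab1 and H2-Aa, which encode both chains of the other class II molecule, had slopes of -0.71 ± 0.12 and -1.80 ± 0.32. The further class II genes H2-Ob and H2-Eb2 had slopes of -1.06 ± 0.19 and -0.10 ± 0.02. In the class I pathway the slope was -1.13 ± 0.20 for H2-K1, a classical class I gene, and -0.41 ± 0.07 for the class I-like gene H2-T22. It was -1.61 ± 0.28 for Psmb9, an immunoproteasome subunit that makes peptides for class I. H2-D1, the other classical class I gene, went the opposite way (0.44 ± 0.08), as did the class Ib gene H2-Q6 (0.67 ± 0.13).

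Called genes without a role in antigen presentation had slopes of either sign. Positive slopes were 0.44 ± 0.07 for Glo1, which detoxifies methylglyoxal, 0.48 ± 0.08 for Fgd2 and 0.27 ± 0.06 for Notch4. Those of the RNA helicase gene Ddx39b, the axonemal dynein gene Dnah8 and the meiotic gene Msh5 were 0.19 ± 0.04, 0.11 ± 0.02 and 0.08 ± 0.02. Negative slopes were -1.27 ± 0.21 for the lipase gene Abhd16a, -0.39 ± 0.07 for Zbtb22 and -0.22 ± 0.04 for Wdr46. Those of the Polycomb gene Ring1 and of Vars2 were -0.08 ± 0.02 and -0.07 ± 0.01. Second probes of H2-K1, Ddx39b and Vars2 did not pass (-0.02 ± 0.02, -0.04 ± 0.05 and 0.05 ± 0.03). Adjusted p of the called genes ran from 0.0041 (Glo1, Fgd2, Wdr46, Abhd16a) to 0.0266 (Msh5, Ddx39b). Other genes of class II presentation did not pass: H2-Eb1 had a slope of -0.07 ± 0.04 (adjusted p = 0.916), the invariant chain gene Cd74 of -0.04 ± 0.03 (0.931) and the class II transactivator gene Ciita of -0.02 (0.976).

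In all, limma called 32 probes for LN MHC Med, 12 with a positive and 20 with a negative slope. Of the 27 with a gene symbol, 26 lay on chromosome 17. The called genes between H2-K1 and H2-D1 numbered 15, out of 67 genes analysed there (assembly GRCm38.p6). The pancreas list moved with this trait (median slope 1.01, 0 genes called by limma over all genes or over the list alone, adjusted p = 0.584 with an estimated correlation). With its score as a covariate 17 probes were called (H2-Ea slope 2.70 ± 0.49, adjusted p = 0.0205). The count was 18 on arrays labelled male, 15 with the first principal component as a covariate and 21 among probes detected on every array. It was 0 with LN T:B as a covariate and in the 15 strains with a pancreas list mean under 9 (limma; 528 and 674 probes at unadjusted p under 0.05). With LN T:B in the model all 32 probes kept an unadjusted p under 0.05. There slopes were smaller and errors larger, as for H2-Ea at 2.05 ± 0.55 and H2-Ab1 at -0.49 ± 0.14 (adjusted p = 0.999 for each). With detection p-values smoothed over intensity, an alternative added later, dim probes had larger slopes. They were -2.08 for Abhd16a, -1.18 for Wdr46, -0.996 for Ring1, -0.89 for Vars2, -0.56 for H2-Eb2, 0.60 for Dnah8 and 0.59 for Msh5.

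**Figure D3:**
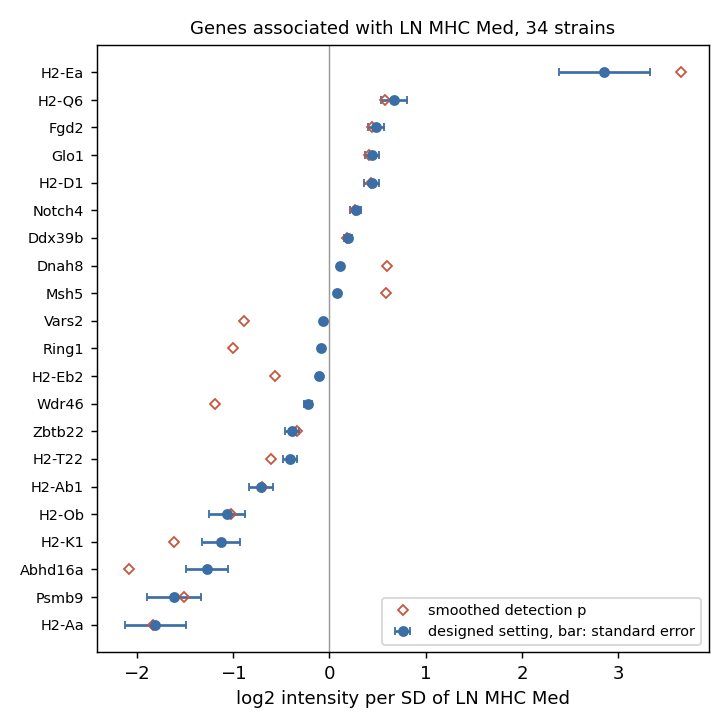
Slopes of the 21 named genes called for LN MHC Med, in log2 intensity per SD of the trait over 34 strains. Filled points with bars are slopes ± SE as designed and open diamonds are slopes with smoothed detection p-values. H2-Ea lies at 2.85 as designed, a size that depends on where background is set.

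The H2 genes did not vary smoothly between strains. H2-Ab1, H2-K1, Psmb9, H2-Ob, H2-Aa and Abhd16a each lay at a lower level on 22 arrays and at a higher level on 16, with no array between. H2-Ea lay between 7.74 and 8.12 on 15 arrays and between 15.51 and 15.94 on 22, with BXD69 alone at 13.19. The 16 arrays of the higher level were the same for H2-Ab1 and Psmb9, and were the 15 low H2-Ea arrays and BXD69. The relations of these genes to a trait are therefore not independent of one another. As the H2 genes lay at separate levels, a pooled correlation with a trait is not given. The levels of H2-Ea lay at background and at the top of the scale, and the lower levels of Psmb9, H2-Aa and H2-K1 lay near background. A relation with a trait could not show there, and the size of every slope given here for these 4 genes depends on where background is set. A relation within a level was read only for both levels of H2-Ab1 and the higher level of Psmb9, H2-Aa and H2-K1, with 14 or 20 strains each. None of these relations with LN MHC Med passed, with a smallest adjusted p of 0.809 (over 10 relations, 5 genes at 2 levels). For H2-Ab1 r was -0.318 over 20 strains of the lower level (permutation p = 0.171; rho -0.302, permutation p = 0.192). Over 14 strains of the higher level it was 0.354 (permutation p = 0.218; rho 0.379, permutation p = 0.18). With LN T:B the smallest adjusted p within these levels was 0.244, over the same 10 relations, some of which could not show. For H2-Ab1 r was -0.439 over the lower level (permutation p = 0.0531; rho -0.484, permutation p = 0.0311). Over its higher level r was -0.00998 (permutation p = 0.971; rho 0.172, permutation p = 0.553). Over the higher level r was -0.521 for Psmb9, -0.493 for H2-Aa and -0.428 for H2-K1 (permutation p = 0.0558, 0.0731 and 0.128).

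**Figure D4:**
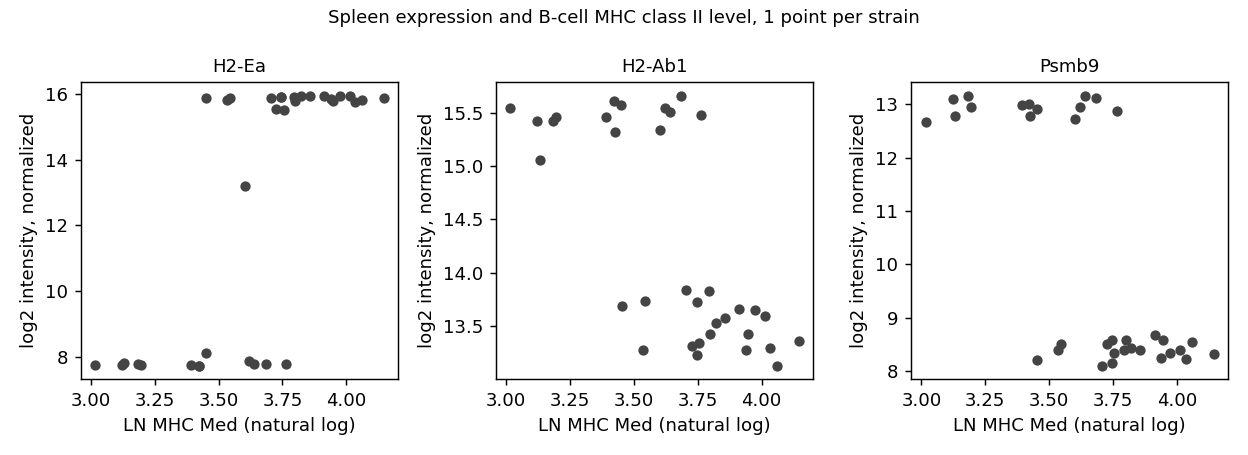
Log2 intensity of H2-Ea, H2-Ab1 and Psmb9 against LN MHC Med (natural log), 1 point per strain, 34 strains. Each gene occupies separate levels with no array between them, apart from H2-Ea in BXD69 at 13.19.

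Of the gene lists tested against LN MHC Med, MHC class II and class I presentation fell in probe signal. Of 11 class II genes measured 9 had negative slopes. Over all genes 1 was called up and 5 down, and adjusted over the list alone also 1 and 5. Camera gave an adjusted p of 3.4e-07 (adjusted p = 0.102 with an estimated correlation), and fry, which asks whether a list moves one way, 0.0253. Of 13 class I genes 12 had negative slopes. Over all genes 1 was called up and 2 down, and adjusted over the list alone also 1 and 2 (camera adjusted p = 6.8e-05, adjusted p = 0.102 with an estimated correlation, fry 0.0253).

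The B cell list fell as well, with 19 of 21 slopes negative and a median of -0.06 (camera adjusted p = 0.000175, adjusted p = 0.584 with an estimated correlation). Its antigen receptor genes Cd79a and Cd79b had slopes of -0.11 and -0.09 (adjusted p = 0.916 for each). The plasma cell list fell, with 10 of 12 slopes negative (camera adjusted p = 0.0171, adjusted p = 0.584 with an estimated correlation). The pancreas list rose, with 15 of 16 slopes positive, for example 1.19 for Cela2a and 1.11 for Cpa1 (camera adjusted p = 1.6e-09, adjusted p = 0.584 with an estimated correlation). Erythroid genes rose, 20 of 21 with positive slopes and a median of 0.13, such as the transcription factor gene Klf1 at 0.37 (camera adjusted p = 6.8e-05, adjusted p = 0.787 with an estimated correlation). Cell cycle genes rose, 18 of 20 with positive slopes and a median of 0.07, such as the replication helicase gene Mcm7 at 0.13 (camera adjusted p = 0.00157, adjusted p = 0.787 with an estimated correlation).

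For these last 5 lists limma called 0 genes over all genes and 0 adjusted over the list alone. With the pancreas list score as a covariate the cell cycle list had a camera adjusted p of 0.0683. In the 15 strains with a pancreas list mean under 9 only the class II and class I lists kept both call and direction (camera adjusted p = 0.0379 for each). There the pancreas list, near background, went the opposite way (1.4e-06), as did the cell cycle list without passing (0.295). The strains were chosen for low values of the pancreas list, so its direction among them is not read. The B cell, erythroid and plasma cell lists did not pass there (0.477, 0.91 and 0.295). With the first principal component as a covariate the pancreas list also went the opposite way and did not pass (0.174), nor did the cell cycle list (0.189). With the erythroid list score as a covariate neither the erythroid (0.818), the plasma cell (0.0598) nor the cell cycle list passed, the last with the opposite direction (0.792). That score is built from the erythroid list itself, so the result for that list was fixed in advance and is not read. With LN T:B as a covariate only the class II (0.0109) and pancreas lists (0.0183) passed. Without the 2 strains farthest from the median LN MHC Med the plasma cell list did not pass (0.447), nor did it with the authors' table without BXD12 (0.0519). T cell genes had an adjusted p of 0.475, and the other lists not named here 0.286 or more. The germinal centre list (0.432) had 1 gene down adjusted over the list alone.

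The ratio of T to B cells was tested in the same way, and H2 genes were again among those called. H2-Ea (2.57 ± 0.52 per SD of LN T:B, SE, n = 34, or 3.26 with smoothed detection p-values) and Notch4 (0.27 ± 0.06) rose. H2-Ab1 (-0.65 ± 0.13), H2-K1 (-1.04 ± 0.21), Psmb9 (-1.47 ± 0.30) and H2-Ob (-0.97 ± 0.20) fell. Also lower in strains with relatively more T cells were the thioesterase gene Ppt2 (-0.21 ± 0.04) and the vesicle tethering gene Vps52 (-0.10 ± 0.02). The same held for the lipase gene Abhd12 (-0.06 ± 0.01), the membrane protein gene Tmem176a (-0.13 ± 0.03) and Parp8 (-0.15 ± 0.03). The lineage genes behind the ratio did not pass. Cd79a had a slope of -0.19 ± 0.05 (adjusted p = 0.135) and Cd79b of -0.12 ± 0.04 (0.158). The T cell receptor complex genes Cd3d, Cd3e and Cd3g had slopes of 0.04 (0.865), 0.10 ± 0.07 (0.571) and 0.01 (0.984). H2-Aa, at -1.62 ± 0.35, missed the threshold (adjusted p = 0.0535).

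Limma called 11 probes for LN T:B, 2 up and 9 down, with adjusted p between 0.0442 and 0.0482 and 2063 probes at unadjusted p under 0.05. Of the 11, 8 lay on chromosome 17. The lists for LN T:B and LN MHC Med shared 7 probes, all 7 with the same sign, where independent lists would share 0.0213. The traits were themselves correlated, so the overlap does not come from independent measurements. With LN MHC Med as a covariate none of the 11 passed, though all 11 had an unadjusted p under 0.05 (H2-Ea slope 1.34 ± 0.55, adjusted p = 0.459). The 1 probe called there was of Itgb2 (-0.15 ± 0.03, adjusted p = 0.0371), named after its value was seen. The pancreas list moved with this trait too (adjusted p = 0.539 with an estimated correlation), and with its score as a covariate 0 probes were called. The slopes changed little there, at 2.40 ± 0.54 for H2-Ea, -1.36 ± 0.32 for Psmb9, -0.57 ± 0.13 for H2-Ab1 and 0.27 ± 0.06 for Notch4 (adjusted p = 0.142 for each). The count was also 0 with labelled sex or the first principal component as a covariate, on arrays labelled male and without BXD98 and BXD14 (limma; in these 5 fits 1095 to 2061 probes at unadjusted p under 0.05). With smoothed detection p-values 26 probes passed, 10 of them among the 11. There Parp8 had a slope of -0.72 and was not called, and the slopes of Vps52, Abhd12 and Tmem176a were -0.52, -0.15 and -0.23.

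B cell genes fell with LN T:B as a list, 18 of 21 with negative slopes and a median of -0.10 (camera adjusted p = 6.1e-05, adjusted p = 0.539 with an estimated correlation). Among them were Cd22, an inhibitory receptor of B cells (-0.17 ± 0.06, adjusted p = 0.235), and Fcrla (-0.11 ± 0.04, 0.183). Of the list 0 genes passed limma's test over all genes and 4 adjusted over the list alone. MHC class II genes fell, 9 of 11 with negative slopes (camera adjusted p = 9.9e-05, adjusted p = 0.399 with an estimated correlation, fry 0.0164). Over all genes 1 was up and 2 down, and adjusted over the list alone 1 and 7. Class I genes fell, 12 of 13 with negative slopes, such as the peptide transporter gene Tap1 at -0.17 (camera adjusted p = 0.00236, adjusted p = 0.399 with an estimated correlation, fry 0.0164). Over all genes 0 were up and 2 down, and adjusted over the list alone 1 and 3.

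Plasma cell genes fell, 12 of 12 with negative slopes, such as the transcription factor gene Irf4 at -0.10 (camera adjusted p = 0.0192, adjusted p = 0.539 with an estimated correlation). Interferon response genes fell, 14 of 16 with negative slopes, such as the RNA sensor gene Ddx58 at -0.14 (camera adjusted p = 0.0192, adjusted p = 0.554 with an estimated correlation). Macrophage genes fell, 11 of 14 with negative slopes, such as the complement gene C1qc at -0.12 and the scavenger receptor gene Marco at -0.22 (camera adjusted p = 0.041, adjusted p = 0.554 with an estimated correlation). Of these 3 lists 0 genes passed limma's test over all genes. All 3 lists rested on BXD98 and BXD14. Without those strains the plasma cell (0.902) and macrophage lists (0.601) did not pass, nor did the interferon list, which then had the opposite direction (0.997; Ddx58 slope -0.05). They also missed the threshold elsewhere: the macrophage list among probes detected on every array (0.0588), on arrays labelled male (0.0736), with normal scores (0.0604) and with the percent of CD3+ (0.0829) or the negative percent of CD79+ cells (0.146). The interferon list did so with those percentages (0.0829 and 0.0544) and with smoothed detection p-values (0.0517). The plasma cell list did so among probes detected on every array (0.108), with the negative percent of CD79+ cells (0.0544) and with smoothed detection p-values (0.0583).

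The pancreas list rose with LN T:B, 16 of 16 with positive slopes and a median of 1.06, such as Pnliprp1 at 1.14 ± 0.52 (camera adjusted p = 5.6e-07, adjusted p = 0.539 with an estimated correlation). Erythroid genes rose, 20 of 21 with positive slopes and a median of 0.23, such as Klf1 at 0.53 ± 0.20 and Hemgn at 0.38 (camera adjusted p = 6.0e-07, adjusted p = 0.539 with an estimated correlation). Cell cycle genes rose, 18 of 20 with positive slopes and a median of 0.12, such as the mitotic kinase gene Plk1 at 0.24 (camera adjusted p = 6.1e-05, adjusted p = 0.554 with an estimated correlation). Of the pancreas, erythroid and cell cycle lists 0 genes passed limma's test over all genes. With the pancreas list score as a covariate the camera adjusted p was 4.1e-05 for the erythroid and 0.00305 for the cell cycle list, while the macrophage list did not pass (0.103). The macrophage list was also lost with the first principal component (0.12) and with LN MHC Med as covariates (0.102), as was the class I list (0.0669 and 0.132). With LN MHC Med the plasma cell list did not pass either (0.149). The pancreas list went the opposite way with the first principal component (0.0669). With the erythroid list score as a covariate the erythroid list did not pass (0.791), nor did the cell cycle list, whose direction turned (0.672). As the score is built from the erythroid list, the result for that list is not read.

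In the 15 strains with a pancreas list mean under 9 only the plasma cell list kept its call and direction for LN T:B (camera adjusted p = 0.00285). There the cell cycle (0.0211) and pancreas lists (0.00394) were called in the opposite direction. The strains were chosen for a pancreas list near background, so the direction of that list is not read. The B cell (0.611) and erythroid lists (0.424) had the opposite direction and did not pass. The other 4 lists did not pass (0.336 or more). Of the pancreas, erythroid, cell cycle, plasma cell and macrophage lists limma called 0 genes over all genes and 0 adjusted over the list alone, and of the interferon list 0 and 1.

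The T cell list, with 7 of 17 slopes positive, was not called (camera adjusted p = 0.816). Nor were CD8 T cells (0.12, with 2 genes down adjusted over the list alone), CD4 T cells (0.504), NK and cytotoxic cells (0.316, with 1 gene down adjusted over the list alone), neutrophils (0.456), dendritic cells (0.316) or megakaryocytes and platelets (0.866). The adjusted p was 0.816 for the germinal centre and marginal zone B cell lists, 0.316 for stroma and capsule, 0.778 for adipose tissue, 0.942 for ribosomal proteins and 0.937 for oxidative phosphorylation. It was 0.942 for immediate early genes, 0.456 for heat shock, 0.318 for glucocorticoid response and 0.942 for the circadian clock.

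The ratio of CD4+ to CD8+ cells gave no called gene. The gene for the beta chain of CD8 itself, Cd8b1, had a slope of -0.43 ± 0.15 (SE, n = 34), which did not pass over all genes (limma unadjusted p = 0.00626, adjusted p = 0.477). A second probe of Cd8b1, also detected on every array, did not share that slope (0.02 ± 0.04, adjusted p = 0.859). None of the 10 genes of smallest p passed. They included the lysosomal lipase gene Lipa (-0.24 ± 0.06), Psip1 (0.15), Polr2d (0.15) and Drg1 (0.13), and Trappc12 (-0.15 ± 0.04, or -0.86 with smoothed detection p-values). Limma called 0 probes, with 1571 at unadjusted p under 0.05. H2-Ea (-0.18, adjusted p = 0.945, or -0.10 with smoothed detection p-values) and H2-Ab1 (0.06, 0.927) showed no such relation to this trait as to the other 2.

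For LN CD4:CD8 camera called 4 gene lists at the preset correlation, none of which passed with an estimated correlation. Cell cycle genes rose, 20 of 20 with positive slopes and a median of 0.11, such as the mitotic genes Aurkb at 0.16 and Birc5 at 0.26 (camera adjusted p = 0.00033, adjusted p = 0.814 with an estimated correlation). Erythroid genes rose, 20 of 21 with positive slopes and a median of 0.13, such as the carbonic anhydrase gene Car2 at 0.30 (camera adjusted p = 0.00566, adjusted p = 0.894 with an estimated correlation). Macrophage genes fell, 12 of 14 with negative slopes, such as the haem oxygenase gene Hmox1 at -0.19 ± 0.08 (camera adjusted p = 0.00566, adjusted p = 0.814 with an estimated correlation). Interferon response genes fell, 13 of 16 with negative slopes, such as Ifit2 at -0.11 (camera adjusted p = 0.00645, adjusted p = 0.814 with an estimated correlation). In each of these 4 lists limma called 0 genes over all genes and 0 adjusted over the list alone, and fry called 0 lists. The pancreas list (camera adjusted p = 0.888) and the remaining lists (0.0709 or more) were not called. Of these, adjusted over the list alone, the plasma cell list had 2 genes up, the dendritic cell list 1 up and 1 down and the class I list 1 down.

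These 4 lists did not hold under every alternative. With the negative percent of CD8+ cells in place of LN CD4:CD8 all 4 had the opposite direction, and the erythroid list was called in it (camera adjusted p = 0.0408). The cell cycle (0.255), macrophage (0.319) and interferon lists (0.576) did not pass there. That percent is of lymphocytes, so it also varies with the share of T cells. It was 26.4 in BXD6, with 56.1% CD3+ cells, and 5.2 in BXD98, with 10.3%. The reversal is therefore not read as a property of the ratio of CD4+ to CD8+ cells. In the 15 strains with a pancreas list mean under 9 only the macrophage list kept its call and direction (0.0037). The erythroid list was again called in the opposite direction (0.00682), and the cell cycle (0.76) and interferon lists (0.285) did not pass. With the erythroid list score as a covariate the erythroid (0.557) and cell cycle lists (0.203) did not pass. For the erythroid list that is not read, as the score is built from it. Without the 2 strains farthest from the median LN CD4:CD8 the interferon list did not pass (0.0982).

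The genes of smallest p for LN MHC Med and LN T:B lay together on chromosome 17, which carries the H2 complex. Of the 100 genes of smallest p for LN MHC Med 46 lay there, where 5.04 would be drawn by chance (one-sided Fisher's exact test, adjusted over all chromosomes and traits 1.1e-31). They were led by H2-Ea, Wdr46, Glo1, Abhd16a, Fgd2 and H2-Ab1. For LN T:B 31 lay there (adjusted p = 2.1e-15), led by Vps52, Ppt2, H2-Ab1, H2-Ea, Notch4 and H2-K1. With the pancreas list score as a covariate these counts were 47 and 27. For the other chromosomes and for LN CD4:CD8 the adjusted p was 0.462 or more. Neighbouring genes are inherited together in these strains and are not independent of one another.

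Sex was compared between the 3 arrays labelled female and the 35 labelled male, which are of different strains, so that sex and strain are partly confounded. The immediate early genes Fos and Dusp1 were among the genes higher on the arrays labelled female. The transcription factor gene Fos was higher by 0.64 ± 0.07 (log2, SE; means 8.68 and 8.04, limma adjusted p = 7.0e-07). The phosphatase gene Dusp1 was higher by 1.17 ± 0.18 (means 12.52 and 11.35, limma adjusted p = 0.000384) and the C-type lectin gene Clec4d by 1.25 ± 0.16 (means 9.29 and 8.04, limma adjusted p = 1.6e-05). Lox, which crosslinks collagen, was higher by 0.99 ± 0.11. The chemokine receptor gene Cxcr1 (0.43 ± 0.06), Acod1 (0.31), Il1r2 (0.31) and Arg2 (0.30) were higher too. The neutrophil and macrophage lists did not pass by labelled sex (camera adjusted p = 0.171 and 0.449). With smoothed detection p-values the differences of these 4 were 2.47, 1.67, 2.08 and 2.01, and those of Fos and Clec4d were 1.48 and 1.92.

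Some of these differences came from BXD18 and BXD38 alone. On BXD96 Cxcr1 lay at 7.78, Acod1 at 7.82 and Il1r2 at 7.80, against means of 7.77, 7.81 and 7.77 on arrays labelled male. Without BXD38 the difference was 0.78 for Clec4d, 0.20 for Acod1 and 0.14 for Il1r2, and it did not pass for Dusp1 (0.91, adjusted p = 0.122) or Arg2 (0.20, adjusted p = 0.0576). Without BXD96 it was 1.80 for Clec4d, 0.64 for Cxcr1, 0.47 for Acod1 and 0.45 for Il1r2.

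In all, limma called 69 probes, 66 higher and 3 lower on arrays labelled female. The count was 46 without BXD18, 12 without BXD38 and 133 without BXD96. The genes that mark sex itself were not among them. Xist, expressed from the inactive X chromosome of females, differed by 1.15 ± 0.49 (limma adjusted p = 0.674). The Y-linked genes Kdm5d and Eif2s3y differed by -0.06 and -0.13 (0.973 and 0.979). Values near background were compressed, and with smoothed detection p-values the differences were 1.76 for Xist, -0.78 for Kdm5d and -1.13 for Eif2s3y (adjusted p = 0.794, 0.831 and 0.741). The direction of all 3 rested on BXD96, without which the differences were -0.16 for Xist, 0.04 for Kdm5d and 0.19 for Eif2s3y (adjusted p = 0.963, 0.929 and 0.801). Xist lay above 11 on 2 arrays, BXD96, labelled female (11.70), and BXD70, labelled male (11.44), and Eif2s3y was at 7.73 on both. BXD18 and BXD38, labelled female, had Xist at 7.76 and 7.78 and Eif2s3y at 8.60 and 8.75. The levels of these genes thus went against the labels of 3 arrays, BXD70, BXD18 and BXD38. Among arrays labelled male Xist also lay at 8.68 on BXD32, 8.59 on BXD65 and 8.20 on BXD75, detected on BXD75 only. Eif2s3y lay at 8.37, 8.13 and 8.62 there. Arrays are named by their labels throughout, and any direction between the labelled sexes rests on those labels.

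**Figure D5:**
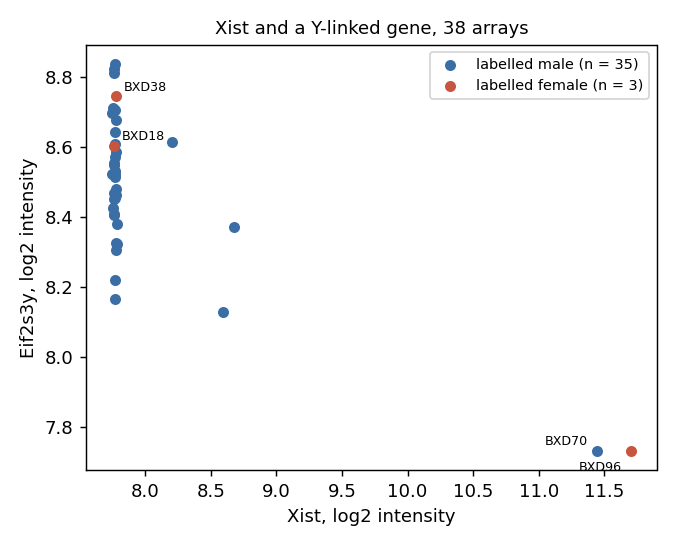
Log2 intensity of Xist against Eif2s3y on 38 arrays, 1 point per strain, coloured by labelled sex. BXD96 and BXD70 lie apart, with Xist at 11.70 and 11.44 and Eif2s3y at 7.73, and BXD18 and BXD38 lie among the arrays labelled male.

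Genes of most lists varied together across the 38 arrays. Of 26 lists 22 had a mean pairwise r above random lists of matched expression. The smallest permutation p that 10000 random lists can give is 0.0001 (adjusted 0.000173), and these r are means over pairs of genes, which are not independent replicates. The pancreas list was highest (mean r 0.901), with Cela3b between 7.73 and 15.70. Groups of blood formation came next. Megakaryocyte and platelet genes had a mean r of 0.713, with the chemokine gene Ppbp from 11.67 to 13.48 and the glycoprotein gene Gp5 from 9.07 to 11.44. Neutrophil genes had one of 0.707, with the granule genes Lcn2 from 8.32 to 14.04 and Elane from 7.85 to 11.22. Cell cycle genes had one of 0.687, with Birc5 from 8.46 to 11.99. Erythroid genes had one of 0.682, with Hemgn from 7.87 to 12.11 and the haem synthesis gene Urod from 12.26 to 14.56.

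Among lymphoid lists, T cell genes had a mean r of 0.518 (Cd3g from 10.93 to 12.72) and B cell genes of 0.34 (Cd22 from 9.78 to 11.36, Ms4a1 from 8.69 to 9.49). Heat shock genes stood at 0.6 (Hsph1 from 9.96 to 12.82), glucocorticoid response genes at 0.569 (Fkbp5 from 8.25 to 10.78) and adipose genes at 0.513 (Adipoq from 7.75 to 10.32). Interferon genes stood at 0.38 (Ifit2 from 8.23 to 9.87) and immediate early genes at 0.349. The glucocorticoid score was 4.24 in BXD38 and 1.05 in BXD18, the next highest array, and the immediate early score 2.73 and 1.55. How far the r of these lists rests on BXD38 was not tested. Lower values were 0.296 for MHC class II, 0.276 for macrophages, 0.275 for NK and cytotoxic cells, 0.259 for CD8 T cells and 0.213 for plasma cells. The lowest that passed were 0.191 for ribosomal proteins, 0.166 for MHC class I, 0.151 for the circadian clock, 0.137 for oxidative phosphorylation and 0.11 for dendritic cells. Some members of the CD8 T cell, plasma cell and circadian lists barely left background, such as Klrk1 (7.75 to 7.86), Eaf2 (7.74 to 7.80) and Ciart (7.75 to 7.79). Others varied above it, such as Cxcr3 (8.28 to 9.57), Creld2 (10.70 to 11.92) and Tef (8.77 to 9.85). The share of the dim members in these r was not tested. CD4 T cell (0.0302), germinal centre (0.0514), marginal zone B cell (0.0708) and stroma and capsule genes (0.0919, adjusted p = 0.053) were not called.

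Unsupervised clustering of the 3000 most variable probes gave 20 modules. Module 1, of 375 probes, joined red cell formation with proliferation. It held 16 of 17 erythroid genes (adjusted p = 9.5e-11, one-sided Fisher's exact test) and 15 of 17 cell cycle genes (3.4e-09), and was led by Pheta2, the haem synthesis gene Uros, Hemgn and Birc5. Module 4, of 96 probes, held 16 of 16 pancreas genes (2.8e-21), with Tmed6, Erp27, Klk1b5 and Prss2. The component of module 12, with the mitochondrial genes Atp5b and Acadm, ran against the pancreas score over the 38 arrays (r = -0.845; rho -0.812; permutation p = 1.0e-05 for each, the smallest these permutations can give; r without the 2 farthest arrays -0.834). Module 15 joined granule genes of developing neutrophils, such as Elane, Mpo, Ngp, Ltf and Camp (10 of 11, 2.1e-18), with platelet genes such as Gp5 (4 of 5, 3.1e-06).

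Module 17 held 3 of 5 glucocorticoid response genes (0.000441) and 2 of 4 immediate early genes (0.0265), with Fkbp5, Pdk4, Ddit4 and Socs3, and 1 array lay apart from the other 37 there. Module 19, of 20 probes, held 4 of 6 MHC class II genes (3.1e-06) with H2-K1, Psmb9 and Abhd16a. Of its 17 probes with a chromosome 13 lay on chromosome 17. Module 20 held histone genes such as H4c6 and H2bc15, with 14 of 19 on chromosome 13. Module 2, led by Mfsd8 and Marchf7, had 270 probes, and module 3, led by the respiratory complex I genes Ndufa2 and Ndufb3, had 139. In module 3, too, 1 array lay apart from the other 37, by 0.643 of the range (0.59 in module 17). Module 7 held 2 of 4 oxidative phosphorylation genes (0.0466).

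Of 60 pairs of a module with a trait, 5 passed. Module 19, the H2 module, was paired with LN MHC Med and with LN T:B (permutation tests, adjusted p = 0.0009 for each). Its arrays fell into levels of 22 and 16, so no pooled r is given. Module 9, which holds Cd79a, the B cell transcription factor gene Pou2f2 and Ptk2b, fell with LN T:B (r = -0.509, permutation p = 0.00295, adjusted 0.0355; rho -0.423, permutation p = 0.0137, adjusted 0.164). Without the 2 strains farthest from the component's median r was -0.351. Module 13, with the bacterial lipoprotein receptor gene Tlr2, Kctd12 and Dram1, fell too (r = -0.497, permutation p = 0.00296, adjusted 0.0355; rho -0.393, permutation p = 0.0225, adjusted 0.169), with r at -0.31 without the 2 farthest strains. Module 6, whose 54 probes have no gene symbol, gave r = -0.523 (permutation p = 0.00209, adjusted 0.0355; rho -0.541, permutation p = 0.00118, adjusted 0.0236), and -0.461 without the 2 farthest strains.

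For modules 9 and 13 rho did not pass, and the relation by r rests in part on the strains left out. Module 13 also ran against the pancreas score over the 38 arrays (r = -0.438, permutation p = 0.00554; rho -0.449, permutation p = 0.00505; r without the 2 farthest arrays -0.409), and module 9 did so by rank (rho -0.406, permutation p = 0.0117; r -0.206, permutation p = 0.221; without the 2 farthest arrays -0.159). Module 19 did so by rank as well (permutation p = 0.00645, adjusted 0.0193), and not by r (permutation p = 0.0303, adjusted 0.0819).

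The erythroid list rose with LN T:B by camera at the preset correlation only (adjusted p = 0.539 with an estimated correlation, fry 0.195). Modules 9 and 13 also ran against the erythroid score. Over the 38 arrays r was -0.68 for module 13 (permutation p = 1.0e-05, the smallest these permutations can give, adjusted over 20 modules 6.7e-05; rho -0.696, permutation p = 1.0e-05, adjusted 1.0e-04; r without the 2 farthest arrays -0.622). It was -0.55 for module 9 (permutation p = 0.00026, adjusted 0.00104; rho -0.553, permutation p = 0.00048, adjusted 0.00137; r without the 2 farthest arrays -0.521). Module 19 was paired with it too (permutation p = 0.00607, adjusted 0.0152; by rank 0.00585, adjusted 0.013), and module 6 was not (r = -0.198, permutation p = 0.237; rho -0.22, permutation p = 0.182; r without the 2 farthest arrays -0.175). In the 15 strains with a pancreas list mean under 9, and with a tree height of 0.4, 0 pairs of a module with a trait passed.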

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

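The settings with smoothed detection p-values, with the pancreas list score, the erythroid list score or the other trait as a covariate, with the 15 strains whose pancreas list mean was under 9 and with the authors' table without BXD12 were chosen only after the data were seen. Of the called genes compared, 0 changed sign. The 20 called lists changed direction in 18 of the comparisons below, 5 of them past the test. The 22 coexpressed lists (18 to 23), the 2 chromosomes and the correlations between traits stayed within 1.5 times or on the same side of their test under each alternative run for them. Of the values recomputed under the alternatives fixed in advance, 1498 stayed on the same side or within the limit, 129 lost a call, 3 gained one, 7, all lists, reversed and 37, not called, changed sign, among them Xist (-0.16), Kdm5d (0.04) and Eif2s3y (0.19) without BXD96. Under those added later the numbers were 784, 120, 2, 11 and 63. Where no cause is named, the cause was not tested.

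The count of 11 probes for LN T:B was 0 with the authors' table, with all probes, with labelled sex or the first principal component as a covariate, on arrays labelled male and without BXD98 and BXD14. It was also 0 with the percent of CD3+ or the negative percent of CD79+ cells, with the pancreas or erythroid score, and in the 15 strains with a pancreas list mean under 9 (limma; 1095 to 3083 probes at unadjusted p under 0.05). It was 29 without background correction, 35 with normal scores, 26 with smoothed detection p-values, 1 (not among the 11) with LN MHC Med as a covariate and 31 with the authors' table without BXD12, so the 0 with that table rested on the 1 column of BXD12. For LN CD4:CD8 the negative percent of CD8+ cells called 1 probe, of Notch4, in place of 0, and each other alternative 0 (944 to 2923 at unadjusted p under 0.05). That percent also varies with the share of T cells, and Notch4 was called for LN T:B, so the call is not read as one for the ratio. The 32 probes for LN MHC Med were 21 among probes detected on every array, where fewer probes were tested, 15 with the first principal component, 18 on arrays labelled male and 17 with the pancreas score. They were 0 with LN T:B as a covariate or in the 15 strains with a pancreas list mean under 9, where fewer strains were fitted (528 and 674 at unadjusted p under 0.05).

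With an estimated correlation camera called 0 lists in place of 9, 4 and 7 for LN T:B, LN CD4:CD8 and LN MHC Med (2, 0 and 2 at unadjusted p under 0.05), and fry called 2, 0 and 2. For LN T:B the estimated correlations ran from 0.0437 (CD4 T cells) to 0.901 (pancreas), above the preset of 0.01. The percent of CD4+ cells gave 8 lists in place of 4, and the negative percent of CD8+ cells 6, of which the erythroid list alone was among the 4, in the opposite direction. Both percentages also vary with the share of T cells and do not stand for the ratio alone. For LN MHC Med the erythroid score left 4 lists and LN T:B as a covariate 2. In the 15 strains with a pancreas list mean under 9, LN MHC Med and LN T:B gave 7 lists each, with 2 of the 7 and 1 of the 9 among them in the same direction. Without BXD98 and BXD14, 6 of the 9 for LN T:B stayed, and the interferon (adjusted p = 0.997), macrophage (0.601) and plasma cell lists (0.902) were lost.

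Directions turned as follows (camera adjusted p). For LN T:B it was the pancreas list with the first principal component (0.0669), the interferon list without BXD98 and BXD14 (0.997) and the cell cycle list with the erythroid score (0.672). In the 15 strains it was the B cell (0.611), erythroid (0.424), cell cycle (0.0211) and pancreas lists (0.00394). For LN CD4:CD8 it was the interferon (0.576), macrophage (0.319), erythroid (0.0408) and cell cycle lists (0.255) with the negative percent of CD8+ cells, which also varies with the share of T cells. The erythroid list also turned with its own score (0.557), which is not read, as the score is built from that list. In the 15 strains the erythroid (0.00682) and cell cycle lists (0.76) turned. For LN MHC Med it was the pancreas list with the first principal component (0.174), the cell cycle list with the erythroid score (0.792), and the cell cycle (0.295) and pancreas lists (1.4e-06) in the 15 strains. For both traits the pancreas list lay near background in the 15 strains by their choice, so its direction there is not read.

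The 69 probes that differed by labelled sex were 37 among probes detected on every array, and between 12, without BXD38, and 133, without BXD96, when 1 array labelled female was left out. The 20 modules were 13 at a tree height of 0.4 and 39 with 5000 probes. The 5 module and trait pairs were 0 at a height of 0.4, 2 at 0.6, 2 with 5000 probes, 3 with Spearman's rho and 0 in the 15 strains with a pancreas list mean under 9. Slide as a block was not run, as no slide is given. For arrays the signal over background sets the limit: the median intensity of undetected probes was 67.9 to 96.9, and slopes of probes near that level were compressed by the background estimate.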

Other observations

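The tests of chance orders and splits, the tests of the H2 probes, the test of the sex of the mice, the gene lists by labelled sex, the Ins2 values with smoothed detection p-values and the search for genes with separate levels were chosen only after the results were seen. Beyond the H2 genes, probes of other genes gave signal at separate levels across the panel. A search for probes with a gap of more than 1 log2 and more than 3 SD between levels, each level on at least 6 arrays, found 46 probes. Of these 46 probes 38 had a symbol, of which 10 lie on chromosome 17. Those 10 include H2-Ea, Psmb9, H2-Aa, Abhd16a, H2-K1, H2-Ob and H2-Ab1 from above. Fcer1g, the signalling chain of Fc receptors, had a gap of 4.64 between 16 lower and 22 higher arrays. The proteasome subunit gene Psmb6 split 19 and 19 with a gap of 4.16, and the ribosomal protein gene Rpl29 15 and 23 with a gap of 3.42. The beta globin gene Hbb-b2 split 23 and 15 (gap 2.22), the NK receptor gene Klrd1 13 and 25 (1.57) and the interferon-inducible GTPase gene Gbp2b 15 and 23 (2.59). The antiviral deaminase gene Apobec3 split 21 and 17 (1.16) and the protease inhibitor gene Serpina1b 17 and 21 (3.17). These genes were chosen after their values were seen. Strain variants under their probes were not tested, so the levels are of probe signal and not shown to be of expression.

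Immediate early genes as a group were higher on the arrays labelled female, with 3 of 9 called (median difference 0.37, camera adjusted p = 3.4e-19, adjusted p = 2.5e-06 with an estimated correlation). Glucocorticoid response genes were higher too, with 4 of 8 called (median 0.71, camera adjusted p = 2.3e-17, adjusted p = 0.00104 with an estimated correlation). The interferon list (camera adjusted p = 0.000225) and the adipose list (0.0314) were also higher, each with an adjusted p = 0.699 with an estimated correlation. The score of both stress lists was 3.44 in BXD38, 1.31 in BXD18 and 0.452 in BXD96, and 0.446 in BXD83, the highest array labelled male. For the glucocorticoid list alone BXD96 did not stand out, at -0.0772 against 0.884 in BXD83 and 0.323 in BXD65, both labelled male.

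Pancreatic enzyme genes were high on some arrays and near background on others, with a list mean from 7.80 to 15.06. The list mean did not follow log2 median intensity over 38 arrays (r = -0.0648, permutation p = 0.7, rho -0.0292, permutation p = 0.863, r without the 2 farthest arrays -0.0938). As 12213 to 14162 of 34492 probes were detected per array, that median lies near background. It therefore speaks to the background level of the arrays, and a difference in the signal of detected probes was not tested. RNA from pancreas tissue in the spleen sample is a candidate source, and the median r of 6 islet hormone probes with the mean of 15 acinar genes was 0.42. The insulin gene Ins2 had r = 0.48 (permutation p = 1.0e-05, the smallest these permutations can give, adjusted over the 6 probes 6.0e-05; rho 0.515, permutation p = 0.00115; r without the 2 farthest arrays 0.493) and was detected on 34 arrays, up to 9.29, or 9.87 with smoothed detection p-values (r = 0.619, permutation p = 2.0e-05; rho 0.515, permutation p = 0.00115; r without the 2 farthest arrays 0.572). As the median lay between the bounds of 0.3 and 0.5 set in advance, with smoothed detection p-values too (0.426), and 3 of the 6 probes were not kept, that test could not decide, and a difference between strains in expression within the spleen could not be told apart from it, since there was 1 pool per strain.

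Probes of the H2 region followed LN MHC Med, with 32 called. Chance orders of the trait are argued against, as 2 of 100 orders, the real one included, gave as many, though the highest of the others gave 39. Pancreas RNA as the whole cause is argued against, as 17 of the called probes stayed past the threshold with the pancreas score as a covariate. Strain variants under the probes may contribute: of 2 second probes of called genes that were detected on every array, 0 shared the slope, with Ddx39b at -0.04 ± 0.05 against 0.19 and Vars2 at 0.05 ± 0.03 against -0.07, and 2 probes are too few to decide. A difference in H2 haplotype between strains, in which H2-Ea is not expressed from the C57BL/6 allele, stays open as an explanation that was not tested, since genotypes were not used here. H2-Ea, H2-Ab1 and Psmb9 divided the strains in the same way, with BXD69 between the levels of H2-Ea.

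The higher stress genes on arrays labelled female went with 69 called probes, and 3 of 100 splits into 3 and 35 arrays, the real one included, gave as many, while the highest of the others gave 810, which points to a structure of the samples. Sex of the mice is argued against, as Xist was high on 1 of the 3 arrays labelled female and that array, BXD96, had the lowest stress score of the 3. An acute stress or handling response that differed between pools is consistent with the other 59 called probes following the 17 list genes over the 35 arrays labelled male (r = 0.617, permutation p = 0.00011; rho 0.516, permutation p = 0.00186; r without the 2 farthest arrays 0.478). That test is weak evidence, since 1000 random probe sets gave a median r of 0.237 and a 95th percentile of 0.517. Mislabelled arrays and strain differences stay open.

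For LN T:B, 1 of 100 trait orders, the real one included, gave 11 probes or more, and the highest other gave 1, so chance orders are argued against. For LN CD4:CD8, with a real count of 0 (limma, 1571 probes at unadjusted p under 0.05; highest other 0), all 100 orders must give as many, so that count decides nothing. In the authors' table the column of BXD12 had r = 0.577 with its own array, against 0.963 or more for the others, and over a block of 527 consecutive entries r was -0.0232 as deposited and 0.971 when shifted by 2. The CD4+ percent of BXD33 exceeds 100, where its ratio and its CD8+ percent of 13.2 imply 34.3. In BXD61 the log ratio of the deposited CD4+ and CD8+ percentages differs from LN CD4:CD8 by 0.233, against 0.119 at most in the other strains with BXD33 left out.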
